A study of Mus musculus with 9 samples.

How the data were processed

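Small RNA libraries came from mouse embryos at embryonic day 9.5 after removal of the heart and the tail bud, with 1 library for each of 8 genotypes of the miR-17~92 cluster and 1 library of undetermined reads. Per the labels' protocols, RNA was extracted with Trizol. The submitters' processing notes name STAR 2.2.0, SAMtools 0.1.19, featureCounts of Subread 1.4.2 and the mouse build mm9, with no parameters. How reads that map to more than 1 place were counted is not given in the sources used here. The deposited table holds 1 signal value per mature miRNA and library, with 1046 rows for 977 accessions. These deposited signal values were not whole numbers. Every value of a column was a whole multiple of what 1 read was worth in it, within 0.001 reads, so that 100% of the values came out whole. The factors by which the authors had divided the reads matched the median-ratio size factors of the recovered reads of all 9 libraries.

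Of the accessions, 57 were listed more than once. Rows of 1 accession whose totals differed by 10% or less were merged and the higher was kept, while 8 accessions whose rows differed by more stayed as separate rows, which left 986 rows. miR-92a-3p was among these 8, and which of its rows stands for which locus is not given in the sources used here. Its higher row was counted with the miR-17~92 cluster after its values had been seen, and its lower row was left out of the sums of the miR-17~92 family and the paralog clusters and of counts outside the cluster, but entered the seed-family total of miR-92. miR-219-5p named in the text is the lower of its 2 rows. Some miRNAs of different accessions had the same or nearly the same values, such as miR-1a-3p and miR-1b-5p, or miR-486-5p and miR-3107-3p. They stayed as separate rows, so counts of miRNAs and of hairpins hold some reads more than once. Deposited values were multiplied by 0.1159 in all libraries, which brought the average total of the 8 genotype libraries to that of RPM values and gives nRPM. Log2 values had a pseudocount of 1 nRPM, which understates changes of low miRNAs.

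The 8 genotype libraries held between 6564471 and 18481380 reads, the library of undetermined reads 3023447. The 10 most abundant miRNAs took between 34.7% and 45.2% of a library. Intervals of single values were exact Poisson intervals and those of ratios exact conditional (Clopper-Pearson) intervals, at 95%, and where a miRNA had 0 reads the share that 3 reads would give is stated. Hairpin positions were taken from the GENCODE annotation of GRCm38, not from the build of the deposited table. In it the cluster lies in Mir17hg on chromosome 14 (plus strand, 115042879 to 115046727), with Mir17 at 115043671 to 115043754, Mir18 at 115043851 to 115043946 and Mir19a at 115044000 to 115044081. Mir20a lies at 115044157 to 115044263, Mir19b-1 at 115044305 to 115044391 and Mir92-1 at 115044427 to 115044506. All 6 hairpins overlap an annotated exon of Mir17hg.

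Genotypes came from the labels. The library of undetermined reads had no genotype and entered no comparison. Libraries with a family deleted were compared with those that kept it by two-sided exact permutation tests on log2 of the summed arms, for the 4 families and for the paralog clusters of miR-106a and miR-106b, with Benjamini-Hochberg adjustment over the 4 and the 8 tests. Each family was deleted in 2 to 4 libraries that also differed in other families, so these p-values measure the spread between single libraries of different genotypes. miRNAs outside the cluster were tested in 1 model with an additive term for each family over the 8 libraries (limma, trend, 3 residual degrees of freedom), among miRNAs averaging 10 nRPM or more, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design fixed before the data were examined assumed counts and named edgeR as the main test. Because the table holds normalised values, limma was used as the main test, and edgeR's quasi-likelihood test on the recovered reads became an added alternative, which called 0 miRNAs outside the cluster for each term. DESeq2's Wald test was another alternative. On simulated data with 551 miRNAs, 200 of them changed, limma recovered 94%, 95.5%, 97% and 95.5% of changes of log2 2 for the miR-17, miR-18, miR-19 and miR-92 terms and called between 1.71% and 2.28% of the unchanged miRNAs.

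Mutant libraries were compared with the wild-type library by size alone, counting miRNAs outside the cluster that averaged 100 nRPM or more and differed by a log2 ratio of 1 or more. Before the data were examined, a rule fixed the miRNAs to be named. It took all members of the 3 clusters, the 10 highest and 10 lowest ratios of the full deletion, the 3 highest and 3 lowest of each other mutant, with an average of 100 nRPM or more and at least 20 reads in either library, up to 5 calls per direction and model term, and the 2 most abundant members of each list. Also fixed beforehand were 19 lists of miRNAs: the miR-17~92 cluster, the clusters of miR-106a, miR-106b and miR-322, the let-7 and miR-15/16 families, pluripotency and early embryo, neural, skeletal and cardiac muscle, erythroid and blood, endothelial, mesenchyme and smooth muscle, epithelial, sensory neuron, liver, Hox-cluster, Dlk1-Dio3 imprinted, Sfmbt2 cluster, and hypoxia and p53. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on average level.

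Alternatives were other scalings (plain totals, totals outside the cluster, median-ratio size factors of the 8 libraries), a pseudocount of 10, other minimum levels, other tests and thresholds, other references and leaving out each library in turn. TMM scaling of the values and the partner arms of the kept hairpins were added after the data had been seen. Intervals and limits at 0 reads cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.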

Results

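Small RNA was sequenced from mouse embryos of an allelic series of the miR-17~92 cluster at embryonic day 9.5. The heart and the tail bud had been dissected off, and the remainder of each embryo was profiled. The cluster encodes 6 miRNA hairpins in the host transcript Mir17hg, which belong to 4 seed families: miR-17 and miR-20a, miR-18a, miR-19a and miR-19b-1, and miR-92a-1. The series held 8 genotypes with 1 library each: wild type, deletion of the miR-17 family (ΔmiR-17), of miR-18a (ΔmiR-18), of the miR-19 family (ΔmiR-19) or of miR-92a-1 (ΔmiR-92), the combined deletions ΔmiR-17,18 and ΔmiR-17,18,92, and deletion of the whole cluster. All 8 were labelled female. The library of 3023447 reads of undetermined genotype entered no comparison.

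Reads assigned to mature miRNAs numbered 7070844 in wild type, 12943617 in ΔmiR-17, 18481380 in ΔmiR-18 and 9288308 in ΔmiR-19. They numbered 6564471 in ΔmiR-92, 9266977 in ΔmiR-17,18, 12342973 in ΔmiR-17,18,92 and 9030396 in the full deletion. Levels are given as normalised RPM (nRPM), the deposited normalised reads multiplied by 0.1159 in every library. A single read was worth between 0.062 nRPM in ΔmiR-18 and 0.157 nRPM in wild type. No genotype had a replicate, so a ratio to wild type compares 2 libraries and not 2 conditions, with no replicate check, and the 95% intervals cover counting error only.

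The deleted miRNAs, which test the genotype labels, were nearly absent from the libraries in which they had been deleted. miR-17-5p, a guide strand with targets in cell-cycle control, stood at 17331 nRPM in wild type. It stood at 0.0586% of that level in ΔmiR-17, 0.0512% in ΔmiR-17,18,92, 0.0581% in the full deletion and 1.04% in ΔmiR-17,18. miR-20a-5p stood at 0.0682%, 0.0279%, 0.0676% and 0.601% of wild type in the same 4 libraries. miR-20a-3p had 1453 reads in wild type and 0 in all 4 of these libraries, where 3 reads would equal between 0.0913% and 0.151% of wild type. miR-18a-5p stood at 10099 nRPM in wild type, at 0.0445% of that in ΔmiR-18 and at 0.719% in ΔmiR-17,18. Its share was 0.0425% in ΔmiR-17,18,92 and 0.172% in the full deletion.

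miR-19a-3p stood at 9621 nRPM in wild type. It stood at 0.157% of that in ΔmiR-19 and 0.0513% in the full deletion. Its partner arm miR-19a-5p had 360 reads in wild type and 0 in both, where 3 reads would equal 0.560% and 0.559% of wild type. miR-19b-1-5p likewise had 609 reads in wild type and 0 in both, where 3 reads would equal 0.331% and 0.330%. miR-19b-3p kept 5.73% (95% interval 5.63 to 5.83) of its wild-type level in ΔmiR-19 and 10.6% in the full deletion. Its hairpin shares a stretch of 25 bases with Mir19b-2 of the X-linked paralog cluster, which was intact, so its values are uncertain as a measure of the deleted locus. miR-92a-1-5p stood at 1442 nRPM in wild type, had 0 reads in ΔmiR-92, where 3 reads would equal 0.0298%, and stood at 0.0865% of wild type in ΔmiR-17,18,92 and 0.0873% in the full deletion. miR-92a-3p was listed in 2 rows that differed in level. The higher, at 199542 nRPM in wild type, was taken for the cluster's copy because it was nearly absent where miR-92 had been deleted (0.437%, 0.274% and 0.342% of wild type), so those percentages are no separate check of the labels.

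**Figure D1:**
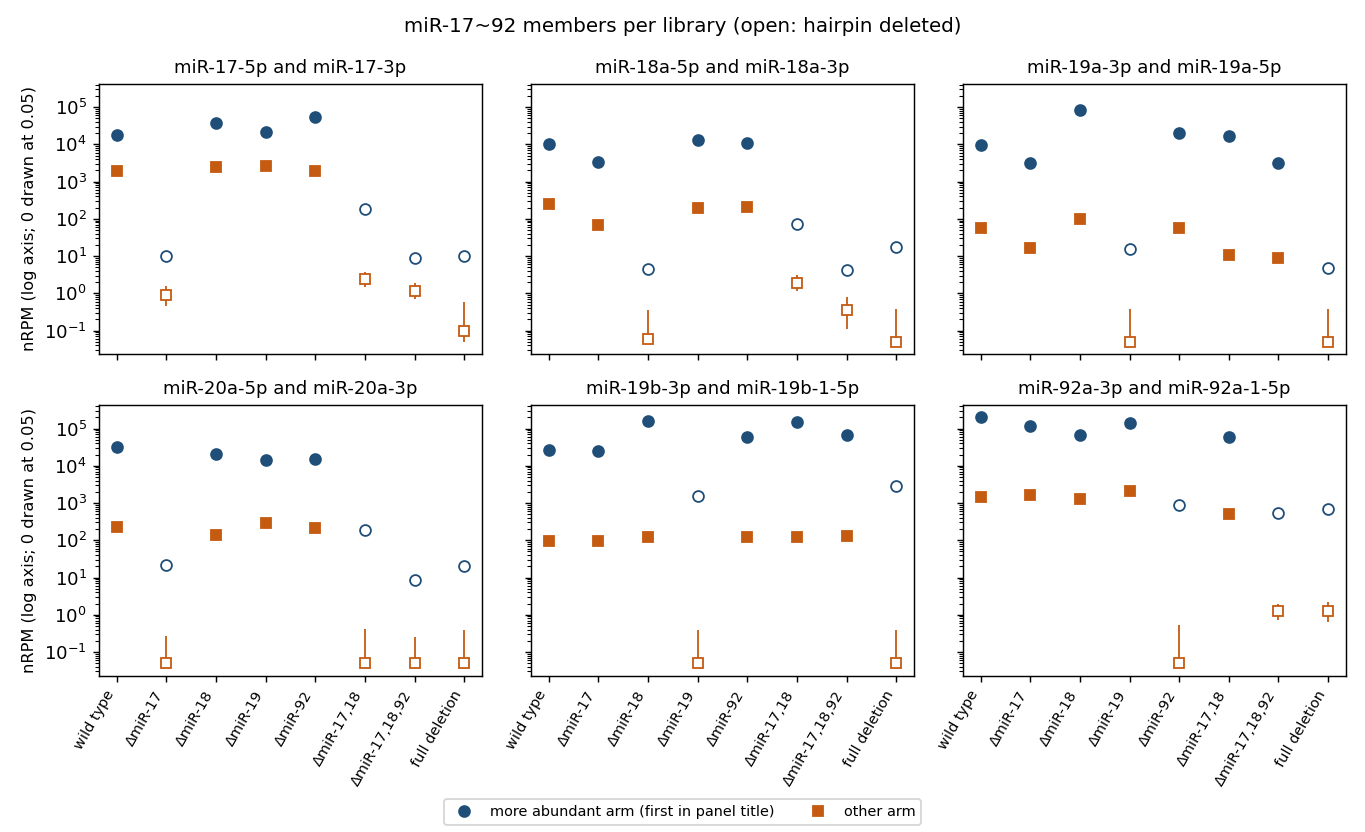
Level of both arms of the 6 miR-17~92 hairpins in each of the 8 libraries, in nRPM on a log axis, with 95% counting intervals. Open symbols mark libraries in which the hairpin was deleted, and miR-20a-3p lay at 0 in all 4 of them.

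Summed over the arms of a family, each family fell in the libraries that lacked it, with no overlap between deleted and intact libraries. The miR-17 family averaged 112.8 ± 171 nRPM (SD, n = 4) where deleted and 55029 ± 13956 nRPM (SD, n = 4) where intact. miR-18a averaged 25.3 ± 33.4 nRPM (SD, n = 4) where deleted and 9408 ± 4095.0 nRPM (SD, n = 4) where intact. The miR-19 family averaged 2206 ± 920.1 nRPM (SD, n = 2) where deleted and 103193 ± 82262 nRPM (SD, n = 6) where intact. miR-92a-1 averaged 700.8 ± 163 nRPM (SD, n = 3) where deleted and 118105 ± 57051 nRPM (SD, n = 5) where intact. That sum was nearly all the higher row of miR-92a-3p (116701 nRPM on average where intact), so its separation was set by the choice of that row. miR-92a-1-5p, which was not chosen by its values, lay at 1.26 nRPM or less where deleted and at 501.8 nRPM or more where intact.

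The mean log2 differences were -9.99, -9.19, -5.22 and -7.28, with every deleted library below every intact one. Two-sided exact permutation tests gave p = 0.0286 for the miR-17 family and for miR-18a, 0.0357 for the miR-19 family and 0.0179 for miR-92a-1. Each is the smallest p its design allows, and all 4 were 0.0357 after Benjamini-Hochberg adjustment of these exact tests. The test of miR-92a-1 restates the choice of its miR-92a-3p row and is no separate check of the labels. Without the full deletion the adjusted exact p was 0.0571 for the miR-17 family and miR-18a, 0.143 for the miR-19 family and 0.0635 for miR-92a-1, and without ΔmiR-19 it was 0.143 for the miR-19 family.

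The limma model with 1 term per deleted family, with Benjamini-Hochberg adjustment, called all deleted arms of the cluster, and over all miRNAs tested it called no other arm of the cluster. Over all miRNAs tested it called 4 of the 12 arms for the miR-17 term, 2 for miR-18, 4 for miR-19 and 2 for miR-92. Those for miR-92 included the miR-92a-3p row that had been chosen for this pattern. Adjusted over the list alone, the counts were 6, 4, 4 and 2, but the arms deleted by design ease that threshold for the kept arms. The additional arms for the miR-17 term were miR-19a-3p (log2 -2.77 ± 0.59 SE, limma adjusted p = 0.00427) and miR-19a-5p (-2.08 ± 0.65, limma adjusted p = 0.0269). Those for the miR-18 term were miR-19a-3p (1.92 ± 0.59, limma adjusted p = 0.0374) and miR-19b-3p (1.92 ± 0.41, limma adjusted p = 0.00662). Over all miRNAs their limma adjusted p lay at 0.196, 0.996, 0.648 and 0.304. DESeq2 called the same deleted arms and, over all miRNAs, 3 arms that had not been deleted. These were miR-19a-3p (log2 -2.81, DESeq2 adjusted p = 0.000309) and miR-19a-5p (-2.49, DESeq2 adjusted p = 0.000819) for the miR-17 term and miR-19b-3p (1.91, DESeq2 adjusted p = 0.0173) for the miR-18 term. All these fits included ΔmiR-19 and the full deletion, where the miR-19 arms were themselves deleted and miR-19a-5p had 0 reads. Effects of other families need not add up there, so the estimates for the miR-19 arms are uncertain. edgeR called 0 arms that had not been deleted and 4, 0, 4 and 2 deleted arms, so it missed both arms of miR-18a (edgeR adjusted p = 0.193).

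The next comparison asked whether removal of one family left the remaining cluster members at the wild-type level. Guide arms that had not been deleted often stood several-fold from wild type. miR-19b-3p was 5.78-fold (5.76 to 5.81) higher in ΔmiR-18, 5.50-fold in ΔmiR-17,18 and 2.21-fold in ΔmiR-92, and stood at 0.936 of wild type in ΔmiR-17. In ΔmiR-17,18,92 it stood at 67216 nRPM and in wild type at 26894 nRPM. miR-19a-3p was 8.63-fold (8.56 to 8.70) higher in ΔmiR-18 and 2.09-fold in ΔmiR-92, and stood at 0.335 of wild type in ΔmiR-17 and 0.328 in ΔmiR-17,18,92 but at 1.75 in ΔmiR-17,18. miR-17-5p was 2.10-fold higher in ΔmiR-18, 3.10-fold in ΔmiR-92 and 1.24-fold in ΔmiR-19. miR-20a-5p of the same family went the other way, at 0.679, 0.492 and 0.448 of wild type in these 3 libraries. miR-92a-3p was the most abundant member in wild type. It stood at 0.582 of wild type in ΔmiR-17, 0.343 in ΔmiR-18, 0.697 in ΔmiR-19 and 0.302 in ΔmiR-17,18. Among the libraries that kept each miRNA, wild type was lowest for miR-17-5p and highest for miR-20a-5p and miR-92a-3p. In these cases the single wild-type library may itself have lain apart.

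Of the 23 pairs of a kept guide arm and a mutant library, 15 differed from wild type by 2-fold or more. Among their partner arms, the other strand of the same hairpins, 5 of 23 did. Median log2 ratios of the kept guide arms were -1.17 in ΔmiR-17, 1.07 in ΔmiR-18, -0.11 in ΔmiR-19, 1.07 in ΔmiR-92, 0.80 in ΔmiR-17,18 and -0.14 in ΔmiR-17,18,92. Those of the partner arms were -0.84, 0.34, 0.40, -0.01, -1.52 and -1.08, so the sign of the medians differed in ΔmiR-19, ΔmiR-92 and ΔmiR-17,18. Scaling to plain read totals turned the guide medians of ΔmiR-19 and ΔmiR-17,18,92 to 0.07 and 0.23 and the partner median of ΔmiR-92 to 0.23. In ΔmiR-17,18 the medians kept opposite signs under all 5 scalings, but they came from different hairpins. Only miR-19a had arms of opposite sign there (log2 0.80 on the guide and -2.30 on the partner). The arms of miR-19b (2.46 and 0.33) and miR-92a (-1.73 and -1.52) shared a sign.

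The arms of a hairpin often moved apart. Over the 6 libraries with miR-19 intact, miR-19b-3p ranged 6.18-fold while its partner miR-19b-1-5p ranged 1.33-fold, between 95.4 and 127 nRPM. miR-17-5p ranged 3.10-fold over its 4 intact libraries and miR-17-3p 1.38-fold. miR-19a ranged 26.3-fold on its guide arm and 11.5-fold on its partner arm, with both arms highest in ΔmiR-18 and lowest in ΔmiR-17,18,92. miR-18a ranged 3.71-fold and 3.74-fold, with its lowest intact level in ΔmiR-17 on both arms, at 0.341 and 0.267 of wild type.

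**Figure D2:**
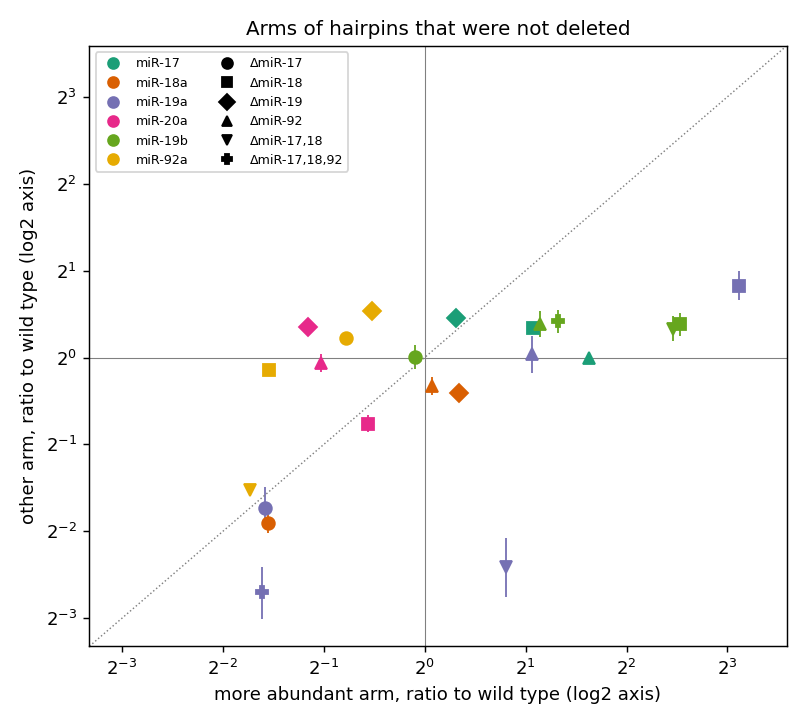
Ratio to wild type of the more abundant arm (horizontal, log2 axis) and of the other arm (vertical, log2 axis) of each hairpin that was not deleted, with 95% counting intervals. Points on the dotted line have both arms at the same ratio, and miR-19b lies between 0.936 and 5.78 horizontally but at most at 1.33 vertically.

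The paralog clusters carry members of the same seed families, and the comparison asked whether they were higher where miR-17~92 members were missing. With the deposited scaling both clusters were higher in all 4 libraries that lacked the miR-17 family than in any of the 4 that kept it, but other scalings broke this separation. The X-linked cluster from miR-106a to miR-363 (X, GRCm38, 52741693 to 52742567) averaged 28835 ± 8960.5 nRPM (SD, n = 4) without the miR-17 family and 20284 ± 2154 nRPM (SD, n = 4) with it. The miR-106b cluster, within the replication gene Mcm7 (chromosome 5, GRCm38, 138164583 to 138172422), averaged 117537 ± 16299 nRPM (SD, n = 4) and 91619 ± 5821 nRPM (SD, n = 4). The log2 differences were 0.47 and 0.35, each with a two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow. After Benjamini-Hochberg adjustment over the 8 exact tests of 2 clusters and 4 families, p was 0.114 for both, so neither passed. For the miR-106a cluster 3 of the 4 libraries remained above all intact ones with plain totals or totals outside miR-17~92 (exact p = 0.0571 in both). For the miR-106b cluster 3 of 4 did with TMM or the median-ratio factors of the 8 libraries (exact p = 0.0571 in both). The other 6 tests had adjusted exact p between 0.286 and 0.786. The full deletion weighed on the difference for the miR-106a cluster, which was 0.27 without it (exact p = 0.0571), against 0.27 for the miR-106b cluster (exact p = 0.0286).

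In the full deletion the miR-106a cluster stood at 1.96-fold (1.95 to 1.97) and the miR-106b cluster at 1.44-fold (1.44 to 1.45) of wild type. Scaled to reads outside the cluster the ratios were 1.65 and 1.21, and scaled to plain totals 2.29 and 1.68. miR-93-5p stood at 76211 nRPM in the full deletion and averaged 31517 ± 8280 nRPM (SD, n = 7) in the other libraries. miR-20b-5p stood at 13689 nRPM against 6837 ± 1456 (SD, n = 7), miR-18b-5p at 11429 against 4489 ± 2921 (SD, n = 7) and miR-106a-5p at 9420.2 against 4700 ± 1736 (SD, n = 7). Of the 11 paralog arms averaging 100 nRPM or more, 5 were highest in the full deletion, among them miR-363-5p at 1944 nRPM. Among the 308 other miRNAs outside the cluster at this level, 55 (17.9%) were highest and 44 (14.3%) lowest in the full deletion. miR-25-3p at 24804 nRPM and miR-93-3p at 103 nRPM were lowest there. miR-106b-5p was highest in ΔmiR-17,18, at 48008 nRPM, and reads of arms that differ by few bases from cluster members could be shared between them by the counting.

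**Figure D3:**
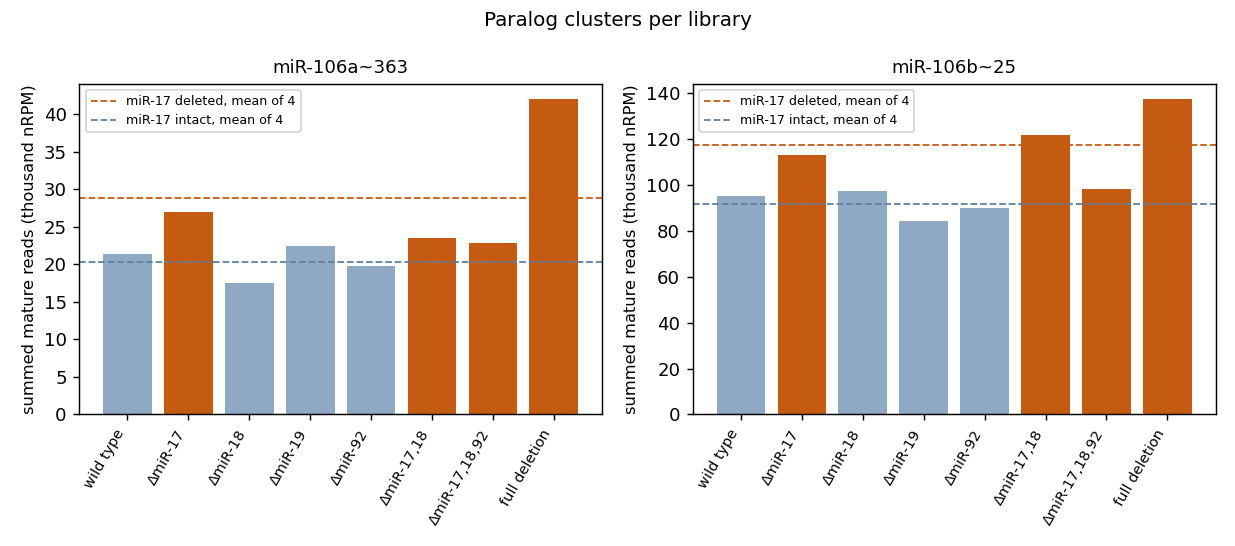
Summed mature reads of the miR-106a and miR-106b clusters in each library, in kilo-nRPM, with dashed lines at the means of the 4 libraries with and the 4 without the miR-17 family. The full deletion has the highest bar for both clusters, at 1.96-fold and 1.44-fold of wild type.

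limma and edgeR called no miRNA outside the cluster for the loss of any family, and DESeq2 called 2 for the loss of miR-19. The limma model over all 8 libraries tested 538 miRNAs outside the cluster and called 0 for the miR-17, miR-18, miR-19 and miR-92 terms. At an unadjusted p under 0.05 it counted 11, 19, 17 and 7. Chance alone would give on average a 0.05 share of the 538. That is more than each of these counts and those of edgeR and DESeq2 below. The lowest limma adjusted p was 0.887 for the miR-17 term, 0.569 for miR-18, 0.484 for miR-19 and 0.990 for miR-92. edgeR on the recovered reads called 0 for each term, with 9, 17, 17 and 7 at an unadjusted p under 0.05. DESeq2 called 0, 0, 2 and 0, with 15, 24, 25 and 17 at an unadjusted p under 0.05. Its 2 calls for the loss of miR-19 were let-7e-5p (log2 -1.49) and miR-219-5p (-1.91), both at a DESeq2 adjusted p of 0.0353, against limma adjusted p of 0.484 and 0.772. let-7e-5p stood at 120 nRPM in ΔmiR-19 and 354.6 nRPM in the full deletion, and at 368 nRPM in wild type.

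Single libraries could change these counts. Without ΔmiR-17, limma called miR-191-5p for the miR-17 term (log2 3.59 ± 0.55 SE, limma adjusted p = 0.0328) and for the miR-18 term (-3.49 ± 0.51, limma adjusted p = 0.032). Without ΔmiR-92, it called miR-539-3p for the miR-17 term (1.97 ± 0.41, limma adjusted p = 0.0493), miR-367-3p for the miR-18 term (2.51 ± 0.44, limma adjusted p = 0.0152) and miR-199a-5p for the miR-19 term (-2.27 ± 0.42, limma adjusted p = 0.0222). These 4 miRNAs were the only calls with 1 library left out, and they are named after their values were seen. The model had 3 residual degrees of freedom. In simulated data it recovered between 94% and 97% of changes of log2 2 but between 26.9% and 56.7% of changes of log2 1. There 200 of 551 miRNAs were changed, which eases the adjusted threshold, so these shares do not hold where few miRNAs change. In the real data miR-494-3p, with a fitted log2 of 1.81 for the miR-92 term, had a limma adjusted p of 0.990.

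The full deletion differed from wild type by 2-fold or more in 53 of the 319 miRNAs outside the cluster that averaged 100 nRPM or more, with 27 higher and 26 lower. With plain totals the split was 43 higher and 14 lower. Among the highest ratios were miR-302c-3p of the pluripotency-associated miR-302 cluster (6.96-fold, 56 to 388 nRPM), miR-539-3p (4.84-fold), miR-7a-5p (3.94-fold, 868 to 3421 nRPM) and the paralog miR-106a-5p (3.61-fold). They were followed by miR-103-3p (3.23-fold, 9410.3 to 30404 nRPM), miR-675-5p, which is processed from the imprinted H19 RNA (2.99-fold), miR-493-3p (2.85-fold) and miR-140-5p, which is known from cartilage (2.68-fold). miR-337-5p and miR-3544-3p, both at 2.95-fold, had the same read counts in these 2 libraries, and their hairpins overlap on opposite strands, so which of them was measured is uncertain.

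The lowest ratios in the full deletion were those of miR-450a-5p of the X-linked miR-322 cluster (0.143, 1724 to 247 nRPM), miR-669c-5p of the Sfmbt2 cluster (0.299) and miR-429-3p of the epithelial miR-200 family (0.306, 1566 to 479 nRPM). miR-493-5p stood at 0.328 and miR-361-3p at 0.341 of wild type. miR-295-3p (0.345) and miR-293-5p (0.361) belong to the early embryonic miR-290 cluster, and miR-142-3p (0.349) is known from blood cells. miR-382-3p (0.357) and miR-23a-3p (0.378) completed the 10 lowest. In 2 cases all 7 mutants lay on one side of wild type by 2-fold or more, miR-302c-3p higher (log2 1.71 to 2.78) and miR-669c-5p lower (189 to 419 nRPM against 840.3), which in each case also means that the single wild-type library lay apart.

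Counts at 2-fold or more in the other mutants were 22 in ΔmiR-17 (9 higher, 13 lower), 47 in ΔmiR-18 (24 and 23), 31 in ΔmiR-19 (11 and 20) and 45 in ΔmiR-92 (22 and 23). They were 77 in ΔmiR-17,18 (37 and 40) and 49 in ΔmiR-17,18,92 (24 and 25). Plain totals gave 21 higher and 10 lower in ΔmiR-17, 19 and 15 in ΔmiR-19, 39 and 19 in ΔmiR-92, and 56 and 13 in ΔmiR-17,18,92. That scaling placed the median of all 319 log2 ratios at 0.24, 0.23, 0.24 and 0.39 in these libraries and at 0.32 in the full deletion, against 0.03, 0.05, 0.01, 0.02 and 0.10 with the deposited scaling. Wild type itself differed by 2-fold or more from the mean of the 7 mutants in 22 of the 319, and each mutant from the mean of the other 7 libraries in between 14 and 31.

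The miRNAs with the most extreme ratios varied between the mutants. In ΔmiR-17, miR-296-3p stood at 0.144, miR-382-5p at 0.163 and miR-181c-3p at 0.162 of wild type, and miR-302c-3p (3.63-fold), miR-539-3p (3.35-fold) and miR-145-5p (2.35-fold) had the highest ratios. In ΔmiR-18, miR-494-3p (0.0826), miR-191-5p (0.101) and miR-295-3p (0.200) were lowest, and miR-367-3p (5.55-fold), miR-135a-5p (4.33-fold) and miR-135b-5p (4.08-fold) highest. In ΔmiR-19, miR-455-5p (0.218), miR-293-5p (0.241) and miR-295-3p (0.259) were lowest, and miR-302c-3p (5.15-fold), miR-675-5p (3.51-fold) and the liver-specific miR-122-5p (3.24-fold) highest. In ΔmiR-92, miR-450a-5p (0.0818), miR-369-5p (0.0898) and miR-455-5p (0.146) were lowest, and miR-367-3p (6.63-fold), miR-302c-3p (4.65-fold) and miR-7a-5p (3.77-fold) highest.

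In ΔmiR-17,18, miR-455-5p (0.129), miR-450a-5p (0.135) and miR-494-3p (0.165) were lowest. The highest ratios there were those of miR-539-3p (8.15-fold), miR-367-3p (7.75-fold) and miR-302c-3p (5.90-fold). In ΔmiR-17,18,92, which kept miR-19a and miR-19b-1 alone, miR-450a-5p (0.135), miR-423-5p (0.182) and miR-669c-5p (0.245) were lowest. miR-1197-3p (8.87-fold, 215 to 1910 nRPM), miR-539-3p (4.75-fold) and miR-122-5p (3.91-fold) were highest there.

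Groups of miRNAs with known tissue or developmental roles were compared as lists. Of the 126 medians of 18 lists in 7 mutants, 21 lay outside the middle 95% of random lists matched on abundance. With a minimum of 100 nRPM the count was 12. By chance 6.3 would if the medians were independent, but all 7 mutants share the wild-type library. Some lists also hold miRNAs of a single cluster, unlike the random lists, so the excess over 6.3 decides nothing. With the mean of the other 7 libraries as reference in place of wild type, 10 of these 21 also lay outside on the same side, and the muscle list in ΔmiR-17 lay outside on the opposite side. These percentiles describe the libraries and test no condition. No member of the 18 lists was called by limma over all miRNAs. Adjusted over the list alone, 1 was called, let-7e-5p for the loss of miR-19 (limma adjusted p = 0.0395), and 0 members of the other 17 lists for any term.

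The erythroid and blood list had its highest median in ΔmiR-18, at log2 1.03 (percentile 99.9), although the red-cell miRNA miR-486-5p stood at 943 nRPM there and 1187 in wild type. The list of mesenchyme and smooth muscle was low in the full deletion (median log2 -0.66, percentile 0.0) and in ΔmiR-92 (-0.46, percentile 1.6). Its member miR-143-3p stood at 9288 nRPM in the full deletion and 14371 in wild type, and miR-199a-3p at 4660 and 6743 nRPM. The muscle list was high in ΔmiR-17,18 (median log2 0.91, percentile 99.5) and ΔmiR-17,18,92 (0.74, percentile 98.2). miR-1a-3p stood at 5005 nRPM in ΔmiR-17,18 and 2485 in wild type, and miR-133a-3p at 752 and 427 nRPM. The same list was high in ΔmiR-17 (0.61) and ΔmiR-18 (0.61) against wild type, but against the other 7 libraries its medians there were -0.46 (percentile 1.4) and 0.18 (percentile 80.8).

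The pluripotency and early embryo list was low in ΔmiR-18 (median log2 -0.77, percentile 0.0), ΔmiR-17,18,92 (-0.38, percentile 1.0), ΔmiR-19 (-0.33, percentile 2.2) and ΔmiR-17 (-0.26, percentile 2.3). Against the other 7 libraries the last pair stood at 0.14 and 0.12. miR-302d-3p stood at 948 nRPM in ΔmiR-18 and 1815 in wild type, and miR-302b-3p at 2147 and 2406 nRPM. The 20 members did not move together. In ΔmiR-18, 2 stood 2-fold or more higher (up to log2 2.47) and 5 lower. Such counts were 2 and 4 in ΔmiR-17,18,92, 2 and 2 in ΔmiR-19 and 1 and 2 in ΔmiR-17. The neural list was high in ΔmiR-18 (0.50, percentile 99.3) and ΔmiR-19 (0.37, percentile 98.0), with miR-219-2-3p at 5087, 4848 and 4077 nRPM in ΔmiR-18, ΔmiR-19 and wild type, and miR-9-5p at 2898, 1037 and 1806 nRPM. Against the other 7 libraries its median in ΔmiR-19 was 0.14 (percentile 82.2). The sensory neuron list, the miR-183 cluster, was low in ΔmiR-17,18 (-0.94, percentile 0.2) and the full deletion (-0.58, percentile 1.6), where it was -0.09 (percentile 20.1) against the other 7 libraries. miR-182-5p stood at 4438, 6211 and 9092 nRPM in ΔmiR-17,18, the full deletion and wild type, and miR-183-5p at 6397, 6905 and 6597 nRPM.

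The list of miRNAs in Hox clusters was low in ΔmiR-92 (median log2 -0.58, percentile 0.7), while its most abundant members miR-10b-5p and miR-10a-5p stood at 33942 and 26987 nRPM there and 35292 and 28278 in wild type. The Sfmbt2 list was low in ΔmiR-17,18 (-0.53, percentile 2.0), with miR-467c-5p at 57.3 nRPM against 88.3. The list of hypoxia and p53 miRNAs was low in ΔmiR-92 (-0.64, percentile 1.0), although miR-210-3p stood at 2104 nRPM there and 1934 in wild type, and miR-34c-5p at 1501 and 1189. The liver list had a single measured member, miR-122-5p, at 69.4 nRPM in wild type and 225, 262 and 271 nRPM in ΔmiR-19, ΔmiR-92 and ΔmiR-17,18,92. Against the other 7 libraries the Sfmbt2, hypoxia and p53, and liver medians given here lay within the middle 95%.

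Against wild type the other 8 lists lay within the middle 95% in all 7 mutants. Against the other 7 libraries the miR-322 cluster in ΔmiR-92 (percentile 1.1) and the endothelial list in ΔmiR-17,18,92 (percentile 1.6) lay outside. Ranges given next are ratios to wild type. Median log2 ratios ranged from -0.02 to 0.56 for the miR-106a cluster, -0.34 to 0.25 for the miR-106b cluster, -0.35 to 0.31 for the let-7 family and -0.33 to 0.03 for the epithelial list. They ranged from -0.72 to 0.59 for the endothelial list, -0.08 to 0.05 for the Dlk1-Dio3 imprinted list, -0.15 to 0.24 for the miR-322 cluster and -0.08 to 0.32 for the miR-15/16 family. let-7a-5p lay between 526.5 and 1149 nRPM over the 8 libraries, miR-126-3p of the endothelium between 6053 and 14901, miR-141-3p of the epithelium between 1166 and 3335 and the imprinted miR-127-3p between 16113 and 29426. miR-503-5p lay between 2603 and 4785 nRPM and miR-16-5p between 3703 and 5352.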

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

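All tests below were chosen after the result was seen, except the comparison of the arms of hairpins outside the clusters, and 4 of them were also revised after their own outcome was known. The transcript test was at first a single median over the 6 hairpins, at 0.835, was then divided by hairpin after the ratios were seen, and last took in the interval of the ratio, widened for the choice among 6 hairpins. The test of less cluster transcript at first used counting error alone and was joined with that of library scaling. The test of a mixed-in library was at first the reads of each arm against 1 common share, then the observed over expected reads of miR-17-3p (at most 0.229 over 3 source libraries). The bound for mixed-in tissue was tightened to count its interval, which turned that explanation from excluded to open.

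The library of ΔmiR-17,18 kept more reads of its deleted members than the other libraries that lacked them, except for miR-20a-3p, which had 0 reads in all 4. miR-17-5p stood at 180 nRPM against 8.9 to 10.1 nRPM in the other 3 libraries that lacked it, a gap of 0.958 of the whole range on log2 values. Reads of paralogs counted at the deleted hairpins were argued against, since miR-17-5p and miR-20a-5p per read of miR-106a-5p and miR-20b-5p were at least 7.7 times the highest of the other 3 libraries. Reads mixed in from an intact library would carry that library's arm ratio, but miR-17-5p outnumbered miR-17-3p by 74.9 (interval 48.8 to 121) against at most 27.7 in a genotype library with miR-17 intact and 31.1 in the undetermined reads. A small amount of intact tissue in the sample may have given them and cannot be excluded, because 4.3% (interval 1.75 to 8.7) of 162 other hairpins had arm ratios as far outside those of the 3 libraries with miR-17 and miR-18 intact. No biological explanation was tested.

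Guide arms of the cluster differed several-fold between libraries in which they were intact, and a change in the amount of the hairpin transcript stays open for all 6 hairpins. For miR-17 and miR-19b, the lowest ratios and picked as such, the spread of the partner arms was at most 0.319 of that of the guide arms, but its upper bound was 1.25 for miR-17, and for miR-19b it was 0.456 alone and 0.686 when widened for the choice among 6 hairpins. For miR-20a, miR-18a, miR-19a and miR-92a the ratio of spreads was 0.789 or more. A bias of single libraries towards single sequences may contribute, since the arms of the 163 hairpins outside the 3 clusters had a median correlation across the libraries of 0.088 (shuffled pairs -0.007). An effect of the deletions on the maturation of the remaining hairpins stays open as well and was not tested here.

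In ΔmiR-17, miR-18a and miR-19a stood at 0.267 to 0.341 of wild type on both arms. Outside the clusters 0.0% of 163 hairpins stood at 50% or less on both arms in this library. That rate does not exclude a bias towards single sequences, because both hairpins were picked after their values were seen. Kept guides of the cluster also differed 2-fold or more from wild type more often (15 of 23) than miRNAs outside it (6.9% to 24.1% per mutant). Library scaling, which moves all miRNAs by 1 factor, was argued against by the partner arms of miR-19b-1 and miR-92a-1. Their counting bounds lay no lower than 0.9099 of wild type. Less cluster transcript stays open, because with the spread between these 2 libraries the bound was 0.448 and miR-92a-3p stood at 0.582. An effect of the deletion of miR-17 and miR-20a on the hairpins that lie between them stays open, because the 3 libraries without miR-17 all lay below the 3 with it on 1 of the 2 arms of miR-19a, miR-19a-5p (12.1 ± 4.3 against 71.3 ± 24.6 nRPM, SD, n = 3 each), but not on miR-19a-3p. With 3 against 3 libraries no exact permutation p under 0.1 is possible, so that test decides nothing. The miR-17 term called both arms with DESeq2 (DESeq2 adjusted p = 0.000309 and 0.000819), but not with limma or edgeR over all miRNAs. It also called both with limma adjusted over the list alone (limma adjusted p = 0.00427 and 0.0269), where the deleted arms ease the threshold. All these fits included libraries in which miR-19a had itself been deleted, so their estimates for it are uncertain.

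Among 28 groups examined for a library far from the others, 2 stood out, where chance gives about 1 in 20. The second was miR-363-5p at 330 nRPM in ΔmiR-17 against 965 to 1944 nRPM in the other 7, a gap of 0.605 of the range on log2 values. Of 16 pairs of backgrounds, 4 had opposite effects of 1 deletion, with 1 library on each side, and these differences were not tested. Deletion of miR-18 gave a ratio of 1.77 for miR-19a-5p with miR-17 intact and 0.628 without it. Deletion of miR-92 gave 2.09 for miR-19a-3p against wild type and 0.188 against ΔmiR-17,18. For miR-19b-3p the same pair of ratios was 2.21 and 0.454. Deletion of miR-17 gave 1.16 for miR-92a-1-5p with miR-18 intact and 0.385 without it. In the undetermined reads the lower row of miR-194-5p stood at 497 nRPM, 3.17-fold above the highest genotype library (157 nRPM).

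The absence of limma calls outside the cluster was set beside other splits of the 8 libraries. With a real count of 0, all 34 splits for miR-17, all 34 for miR-18 and all 56 for miR-92 had to reach it, so these counts decide nothing, and the highest other split called 1, 1 and 0 miRNAs. At an unadjusted p under 0.05 limma counted 11, 19 and 7 for the real splits, and 29 of 34, 22 of 34 and 49 of 56 splits counted as many or more, up to 75, 78 and 74. What the splits with the most miRNAs have in common was not tested. For miR-19, deleted in 2 libraries, limma counted 17 for the real split, and 20 of 28 splits counted as many or more, up to 57.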

How the results depend on the processing

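TMM scaling and the partner arms were alternatives added after the data had been seen. edgeR, the main test of the planned design, became an alternative because the table held normalised values. Of 501 pairs of a result and an alternative, 35 changed by the rules used, with 5 weaker, 6 stronger, 23 moved and 1 median of 2-fold or more reversed, and of 184 scalings of single kept arms 7 changed a sign of any size. Leaving out each library in turn gave differences from -10.92 to -9.51 for the miR-17 family, -9.99 to -8.73 for miR-18a, -5.65 to -4.78 for the miR-19 family and -7.49 to -7.06 for miR-92a-1. Without the full deletion they were -9.75, -9.31, -5.65 and -7.28, and without ΔmiR-19 -4.78 for miR-19, where fewer libraries made the smallest possible p too large after adjustment. For the miR-17 to miR-92 terms the miR-106a cluster ranged over 0.27 to 0.56, -0.09 to 0.33, 0.04 to 0.94 and -0.06 to 0.49, and the miR-106b cluster over 0.27 to 0.43, 0.15 to 0.33, -0.28 to 0.43 and -0.11 to 0.20. Calls by limma outside the cluster ranged from 0 to 1 for miR-17, miR-18 and miR-19 and were always 0 for miR-92. DESeq2 called 2 for miR-19, and the cause was not tested. With a minimum of 10 nRPM the counts of miRNAs at 2-fold or more were 60, 90, 76, 91, 126, 109 and 98 in ΔmiR-17, ΔmiR-18, ΔmiR-19, ΔmiR-92, ΔmiR-17,18, ΔmiR-17,18,92 and the full deletion, because more miRNAs entered. With a minimum of 500 nRPM they were 9, 22, 15, 17, 41, 23 and 24, because fewer did. Against the mean of the other 7 libraries, counts from ΔmiR-18 to the full deletion were 21, 14, 25, 31, 16 and 24, and the cause was not tested. Partner arms had medians of -0.01, -1.52 and -1.08 in ΔmiR-92, ΔmiR-17,18 and ΔmiR-17,18,92. The first pair was opposite in sign to the guide medians, and the cause was not tested. With a minimum of 100 nRPM, 12 list medians lay outside the random range and fewer miRNAs were compared. No paired analysis was possible because every genotype had 1 library, all numbered 1. At these depths 3 reads equal 0.187 to 0.470 nRPM, so depth limits only the rarest miRNAs, and the single library per genotype limits the rest.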

Other observations

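The seed-family totals, the miRNAs that stood apart in 1 library and the comparison with undetermined reads were chosen after the data had been seen. Guide strands that share a seed can act on the same targets, so totals over the 3 clusters were compared. The guides of the miR-17 seed family summed to 107165 nRPM in wild type and 133650 nRPM in the full deletion, 1.25-fold, or 1.05-fold when scaled to reads outside the cluster. Libraries without the cluster's miR-17 family averaged 94562 ± 30625 nRPM (SD, n = 4) and those with it 114919 ± 19124 nRPM (SD, n = 4), a log2 difference of -0.32 (two-sided exact permutation p = 0.257, also 0.257 after Benjamini-Hochberg adjustment over 4 exact tests). The miR-18 guides averaged 5187 ± 4285 nRPM (SD, n = 4) and 14780 ± 2916 nRPM (SD, n = 4), a difference of -1.81 (exact p = 0.0286, adjusted 0.0476). The miR-92 total also held the lower row of miR-92a-3p. The miR-19 guides differed by -5.21 (exact p = 0.0357, adjusted 0.0476) and the miR-92 guides by -1.85 (exact p = 0.0179, adjusted 0.0476), and the exact p was the smallest possible for these 3 families. The miR-19 total held only miR-19a-3p and miR-19b-3p, the guides of the deleted family itself. Its test therefore repeats that of the deleted family. The miR-92 total included the higher row of miR-92a-3p, chosen because it was nearly absent where miR-92 had been deleted. That choice weighed on its test. In the full deletion the totals stood at 0.675 of wild type for miR-18, 0.0782 for miR-19 and 0.150 for miR-92.

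Some miRNAs outside the cluster stood 2-fold or more from all other 7 libraries in a single library. miR-196b-5p, encoded in a Hox cluster, stood at 183 nRPM in ΔmiR-92 and between 556 and 935.5 nRPM elsewhere. miR-199a-5p, known from mesenchyme, stood at 6517 nRPM in ΔmiR-17,18,92 and between 627 and 2277 nRPM elsewhere. miR-191-5p stood at 401 nRPM in ΔmiR-18 against 3102 to 5754 nRPM, and miR-296-3p at 852 nRPM in ΔmiR-17 against 3674 to 5902 nRPM. miR-142-3p of blood cells stood at 849 nRPM in ΔmiR-18 against 114 to 328 nRPM.

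The undetermined reads made up 3.44% of the reads of all 9 libraries. They held miR-17-5p at 20168 nRPM, miR-18a-5p at 6666 nRPM, miR-19a-3p at 23218 nRPM, miR-19b-3p at 75930 nRPM and the higher row of miR-92a-3p at 90095 nRPM, each within the range of the genotype libraries that kept it. miR-20a-5p at 13036 nRPM lay below the lowest of these (13908 nRPM), and the lower row of miR-92a-3p at 31033 nRPM lay above the highest genotype library (22952 nRPM). Their log2 levels differed from the mean of the 8 with an SD of 0.689, and from single libraries with an SD of up to 0.940.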
